A study of Mus musculus with 6 samples.

How the data were processed

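RNA-seq was performed on mesenchymal stem cells (MSCs) cultured from the bone marrow of 3-week-old mice, with 3 libraries from wild-type (WT) mice and 3 from mice with a conditional knockout of Mapk7 (CKO). Per the labels' protocols, cells were expanded in α-MEM with serum, RNA was extracted with TRIzol, and stranded mRNA libraries were prepared with a TruSeq kit for Illumina sequencing. Per the labels, WT library 2 was taken at passage 7 and the other 5 libraries at passage 5. The descriptions give WT libraries 1 and 2 the same animal label. The animal number of WT library 3 differs between its description and its file header. Groups and replicate numbers were taken from the sample titles. The labels do not state that the libraries of a group came from separate litters or culture days, so p-values measure the spread between these libraries only.

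The authors deposited 1 expression value per gene and library, in units of RPKM (reads or fragments scaled to gene length and library total). The file headers call the values only expression, and the unit was worked out from the values: with 1 whole-number total per library and 1 whole-number length per gene, 15056 of 15063 genes (99.95%) gave whole reads in the 6 libraries, within 0.01 read or, for large counts, a relative error of 1e-07. None of 500 genes with values shuffled between genes did so (0% whole). The recovered totals were 17351907, 20689481 and 17352121 in WT libraries 1 to 3 and 18938287, 19345817 and 17751778 in CKO libraries 1 to 3, and 99.1 to 99.6% of each total lay in the listed genes. In simulated data the recovery was exact for 98.1% of 800 genes. A gene of 1 kb with 3 reads has an RPKM of 0.145 to 0.173, which is the precision at low values and covers counting error only. The genome build was mm9 per the submitters' processing notes. The aligner, the counting tool, the gene annotation, the use of strand and any filter applied before deposit are not given in the sources used here. Overlapping, antisense and near-identical genes may therefore share reads. The reference annotation at hand was of another build, so no coordinates are given. A table of the whole series repeated the same values and was not used.

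Expression was tested on log2(RPKM + 1), without further normalization, in the 11085 genes with an RPKM of at least 1 in at least 3 of the 6 libraries. The fit used limma 3.58.1 in R 4.3.3 with genotype as the only term, an intensity trend and robust moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The planned design had foreseen a count model, with this limma fit as the stated substitute if the files held normalized values. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Gene lists were tested as sets with limma's camera at a preset inter-gene correlation of 0.01, for the lists with at least 5 tested members, and again with an estimated correlation and with fry. The 29 lists (551 distinct genes, 503 listed in the files and 412 tested), the design and the rule for named genes were fixed before the data were examined. The lists cover osteoblast, adipocyte and chondrocyte lineage genes, Wnt components, β-catenin targets, the MAPK7 cascade, immediate early genes, stromal markers, smooth muscle genes, matrix, metalloprotease, BMP and TGF-β, Notch, YAP/TAZ, cell cycle, p53, inflammatory, interferon, glycolysis, sterol synthesis and unfolded protein response genes, and markers of macrophages, osteoclasts, granulocytes, lymphocytes, erythroid, endothelial and skeletal muscle cells. A list of Y-linked genes and Xist only described the animals and was not tested as a set. Members were also adjusted over their list alone, without correction across the 29 lists. Such calls do not control error over the lists.

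Genes are named by this rule: Mapk7, Lrp6 and Ctnnb1; up to 12 genes per direction that pass the threshold with a mean RPKM of at least 1 and no overlap between groups or, where fewer than 5 pass, the 5 with the lowest p in that direction; up to 4 members per list with the lowest p; and a set of canonical lineage genes (Runx2, Sp7, Alpl, Col1a1, Bglap, Spp1, Pparg, Cebpa, Fabp4, Adipoq, Lpl, Axin2 and Lef1). Any other gene is said to be chosen after its values were seen. Some genes that the rule takes are not reported here.

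Alternatives were median centring, quantile normalization, no filter, a stricter filter, a pseudocount of 0.1, limma without trend and robust moderation, other thresholds, leaving out each library, merging the WT libraries that share an animal label, and the replicate number as a block. The pseudocount of 0.1, limma without trend and robust moderation, and other thresholds were run for genes only. A limma-voom fit on the recovered reads, a fit with the macrophage marker level as a covariate, and the estimated correlation together with each other alternative run for lists were chosen after seeing the data. The test was tried on simulated data in 20 runs of 11085 genes, with 200 genes changed per run at the real libraries' spread. It recovered 69.8% of genes changed by 2 on the log2 scale and 93.9% of those changed by 4, and 4.8% of its calls were false. The changed genes were drawn at random, so most carried a typical spread (median residual SD 0.346 over the tested genes). Some real genes with large log2 differences spread far more: Comp (−7.22, SE 0.95) and Cnmd (−7.28, SE 1.64) did not pass. The recovery rates do not hold for such genes. A shifted list was recovered in 20 of 20 runs, with 1 false list call in all runs. The simulated genes varied independently, so these runs do not show how often correlated genes give false calls. In the real data the estimated correlation of the lists called by camera ran from 0.19 to 0.85. No library was a copy of another of its genotype: 0.59 to 0.98% of the genes with at least 10 recovered reads over a pair had equal reads in both. Plots were drawn with matplotlib 3.10.9.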

Results

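Gene expression was measured by RNA-seq in cultured bone marrow MSCs, the stromal progenitors that can form bone, cartilage and fat cells, from 3 WT and 3 CKO libraries. Mapk7 encodes ERK5, a MAP kinase that activates MEF2 transcription factors and drives transcription of Klf2 and Klf4. The series title places Lrp6, a Wnt co-receptor, and β-catenin downstream of Mapk7 in the balance of bone and fat, and the comparison of genotypes addresses that axis. Each library held 17351907 to 20689481 counted reads. Values are given in RPKM as mean ± SD over n = 3 libraries per genotype. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the moderated test of limma was used across genes.

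The libraries held stromal and macrophage transcripts in both genotypes. Col1a1, the main bone and fibroblast collagen gene, ranged from 1126 to 2959 RPKM. Lyz2, the macrophage lysozyme gene, ranged from 321 to 2948 RPKM, and this gene was chosen after its values were seen. The 22 monocyte and macrophage markers averaged 3.96 ± 0.99 in WT and 3.78 ± 1.10 in CKO on the log2(RPKM + 1) scale. They were highest in WT library 3 (4.98) and CKO library 3 (4.92), and none passed the test. The list was not called as a set over the 6 libraries (median log2 difference −0.23, camera adjusted p = 0.355). It passed as lower in CKO without WT library 2 (median −0.68, adjusted p = 0.00405) or CKO library 3 (−0.81, adjusted p = 1.71e-04), but not with an estimated correlation (adjusted p = 0.579 and 0.569). Its median was −0.39 without WT library 1, −0.07 without CKO library 1, 0.28 without WT library 3, 0.33 without CKO library 2 and −0.46 with the WT libraries of 1 animal label merged. WT library 2, from passage 7, stood apart: its Pearson correlation with the other libraries across genes was 0.795 to 0.920, and the first principal component (51.0% of variance) set it at 76.4, with the next library at 21.3. WT library 1 and CKO library 1 were the closest pair, at 0.972. The 30 cell cycle genes averaged 1.25 in WT library 2 and 3.49 to 4.60 in the others. The 4 Y-linked genes tested (Ddx3y, Uty, Kdm5d and Eif2s3y) were near 0 in WT library 1, where Ddx3y was at 0.0357 RPKM against 6.46 to 19.1 RPKM in the other 5 libraries.

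Mapk7 transcripts were lower in the CKO libraries but were not absent. Mapk7 averaged 7.65 ± 1.24 RPKM in WT and 4.96 ± 0.969 RPKM in CKO. By library the values were 7.12, 6.76 and 9.07 RPKM in WT and 5.59, 3.84 and 5.45 RPKM in CKO, so the groups did not overlap. Behind them were 409 to 521 recovered reads per WT library and 246 to 350 per CKO library. Klf2, a transcription factor gene induced by ERK5 signalling, averaged 48.3 ± 21.6 RPKM in WT and 2.37 ± 0.942 RPKM in CKO. Klf4, a related target, averaged 12.6 ± 0.997 RPKM in WT and 4.72 ± 2.41 RPKM in CKO. The log2 difference was −0.54 (SE 0.23) for Mapk7, with limma adjusted p = 0.505, −3.79 (SE 0.42) for Klf2, with adjusted p = 0.0765, and −1.32 (SE 0.30) for Klf4, with adjusted p = 0.277. None of the 12 tested members of the MAPK7 cascade list passed over all genes, while Klf2 and Klf4 passed as lower when adjusted over the list alone. Mef2a, which encodes an ERK5 substrate, was at 9.60 ± 0.965 RPKM in WT and 7.88 ± 1.37 RPKM in CKO. As a set the list was not called (camera adjusted p = 0.13), with 7 members above and 5 below 0, but it passed as lower without WT library 2 (adjusted p = 0.0114, and 0.446 with an estimated correlation). Without WT library 1, WT library 3, CKO library 1 or CKO library 2, Klf2 but not Klf4 passed over the list alone. Gene-level RPKM does not separate deleted from retained exons of Mapk7.

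Across all genes, Galnt16 alone passed the test. Galnt16, a gene for an enzyme that starts O-linked glycosylation, rose from 0.558 ± 0.408 RPKM in WT to 12.2 ± 0.740 RPKM in CKO (log2 difference 3.11, SE 0.25, limma adjusted p = 0.0329), and was higher in 3 of 3 CKO libraries. The other 4 genes with the lowest p among those higher in CKO did not pass. They were Lrrc15, a marker of myofibroblast-like stroma, at 0.382 ± 0.341 RPKM in WT and 11.96 ± 4.36 RPKM in CKO (adjusted p = 0.0641), Map3k7cl at 0.585 ± 0.207 and 6.99 ± 2.18 RPKM, Cntfr, a ciliary neurotrophic factor receptor gene, at 0.164 ± 0.0966 and 2.81 ± 0.532 RPKM, and Mogat2, an acyltransferase gene of triglyceride synthesis, at 1.04 ± 1.08 and 12.5 ± 5.83 RPKM. The 5 genes with the lowest p among those lower in CKO also did not pass. Prelp, a matrix proteoglycan gene of cartilage and connective tissue, was at 386 ± 204 RPKM in WT and 7.54 ± 6.01 RPKM in CKO (log2 difference −5.60, adjusted p = 0.0641). Prg4, which encodes lubricin, was at 43.2 ± 25.5 and 2.10 ± 0.907 RPKM (adjusted p = 0.0765). Rarres1 was at 6.66 ± 2.40 and 0.395 ± 0.331 RPKM, and Ibsp, the bone sialoprotein gene, at 8.66 ± 4.53 and 0.0454 ± 0.0309 RPKM. Klf2 was the remaining gene. At an unadjusted p under 0.05 in limma, 1080 of 11085 genes differed, 372 higher and 708 lower in CKO, where chance gives 554 on average. Splits of the libraries that mix the genotypes gave 97 to 1650 such genes, so an excess over 554 need not come from genotype. In 16.7% of genes the 3 CKO values lay all above (833) or all below (1018) the 3 WT values. Chance gives 10% on average over splits, and the share was not computed for the splits that mix the genotypes. An excess over 10% need not come from genotype either. The median log2 difference of all tested genes was 0.034. The number of genes past the threshold was 24 without WT library 1 and 17 without CKO library 1, and 0 with limma without WT library 2, WT library 3 or CKO library 3, where 642, 665 and 800 genes had an unadjusted p under 0.05. Without CKO library 2 it was 1, Plac9a, a gene chosen after its values were seen, and Galnt16 missed the threshold (adjusted p = 0.237).

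**Figure D1:**
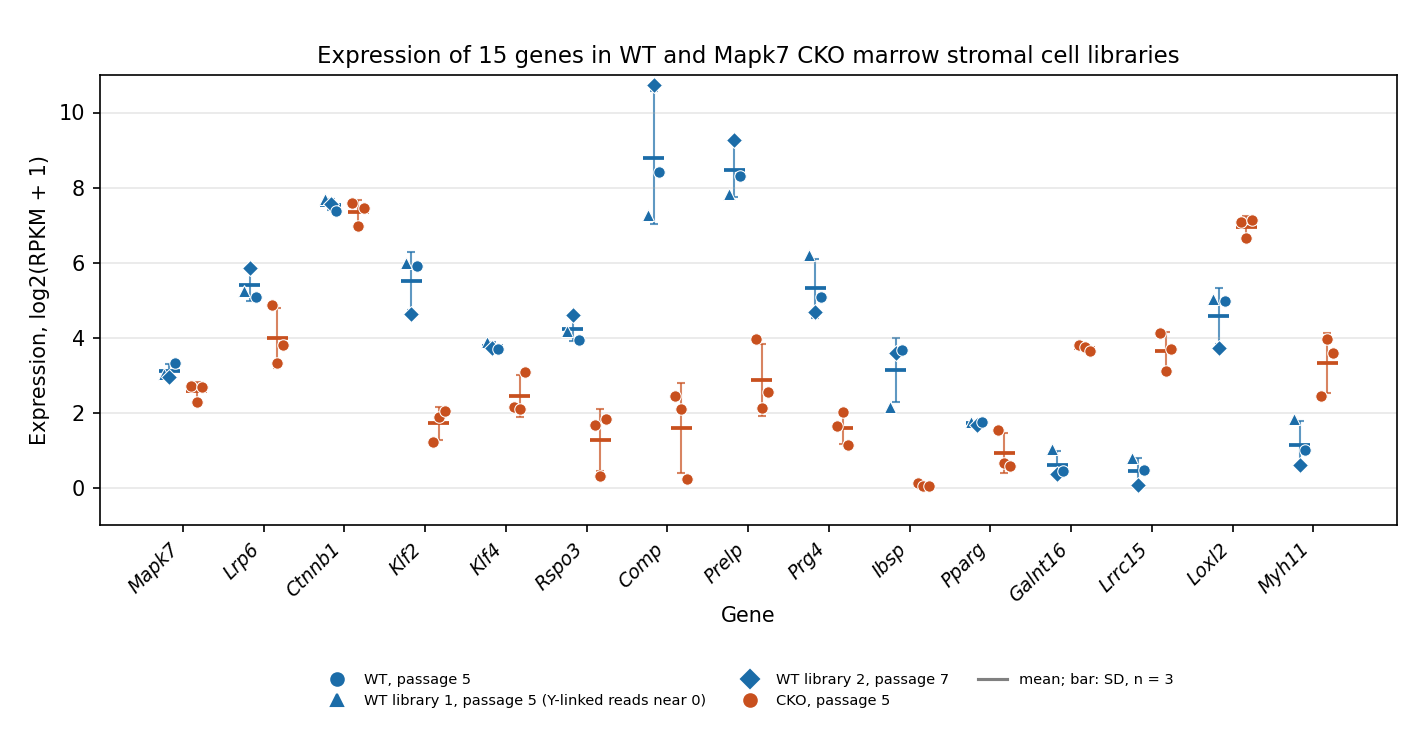
Expression of 15 genes in each library, as log2(RPKM + 1) on the vertical axis, with WT in blue and CKO in orange, bars for the mean and SD over n = 3, a triangle for WT library 1 and a diamond for WT library 2 (passage 7). The 3 CKO points of Klf2 (1.31 to 3.10 RPKM) lie below the 3 WT points (23.5 to 62.3 RPKM), and those of Galnt16 (11.4 to 12.9 RPKM) lie above theirs (0.295 to 1.03 RPKM).

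Of the Wnt components named in the series title, Lrp6 was lower in each CKO library than in any WT library, and the values of Ctnnb1, the β-catenin gene, overlapped. Lrp6 averaged 42.2 ± 12.9 RPKM in WT and 16.7 ± 10.2 RPKM in CKO, with 28.3, 8.96 and 12.8 RPKM in CKO libraries 1 to 3 and 32.9 to 56.9 RPKM in WT. Ctnnb1 averaged 185 ± 19.0 RPKM in WT and 164 ± 34.4 RPKM in CKO. Over the 30 tested Wnt ligands, receptors and secreted antagonists, the median log2 difference was −0.63, and 23 members lay below 0. Rspo3, a Wnt-enhancing ligand gene, was at 18.2 ± 4.50 RPKM in WT and 1.65 ± 1.24 RPKM in CKO. The receptor gene Fzd1 was at 35.2 ± 8.30 and 11.1 ± 5.08 RPKM, Fzd8 at 48.2 ± 27.7 and 7.69 ± 5.69 RPKM, and Fzd9 at 18.9 ± 20.6 and 0.360 ± 0.153 RPKM. Lrp6 did not pass (log2 difference −1.40, SE 0.42, limma adjusted p = 0.336), nor did Ctnnb1 (−0.20, SE 0.28, adjusted p = 0.827). None of the 30 Wnt members passed over all genes. Adjusted over the list alone, 10 did: 9 were lower, among them Lrp6, Rspo3, Fzd1, Fzd8 and Fzd9, and Dkk2, a Wnt antagonist gene chosen after its values were seen, was higher (1.43 ± 1.02 RPKM in WT, 6.61 ± 2.67 RPKM in CKO). The lower members included antagonists as well as activators: Sfrp2, also chosen after its values were seen, was at 107 ± 6.50 RPKM in WT and 18.4 ± 30.9 RPKM in CKO. As a set the list passed as lower (camera adjusted p = 6.97e-06), but not with an estimated correlation (adjusted p = 0.515). The median was −0.96 without CKO library 1. Fzd9 was below the filter, and so not tested, with any 1 WT library left out and with the filter at RPKM 5. The 10 members over the list alone became 12 without CKO library 1, 6 without WT library 1, 5 without CKO library 3, 2 without WT library 3 and 1 without WT library 2 or CKO library 2, and were 6 with the filter at RPKM 5 and 5 without a filter, with voom on recovered reads or with a macrophage covariate.

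Of 16 tested β-catenin target genes, 7 lay above and 9 below 0. Lgr5, a receptor gene for R-spondins, was at 55.8 ± 71.1 RPKM in WT and 0.525 ± 0.584 RPKM in CKO, and Ccnd1, the cyclin D1 gene, at 99.3 ± 42.3 and 30.5 ± 13.0 RPKM. Id2 was at 42.5 ± 10.7 and 19.4 ± 3.95 RPKM. Ccn4, a matricellular gene, was at 23.3 ± 14.7 RPKM in WT and 51.6 ± 11.4 RPKM in CKO. None of the 16 passed over all genes, and Lgr5, Ccnd1 and Id2 passed as lower when adjusted over the list alone. That count of 3 was 0 without WT library 3 or any 1 of the CKO libraries and 2 without WT library 2, and without WT library 1 it was 2 lower and 1 higher. It was also 0 without the filter on low values and with voom on recovered reads, 3 lower and 1 higher with the filter at RPKM 5, and 3 lower and 3 higher with the WT libraries of 1 animal label merged. The list was not called as a set (camera adjusted p = 0.251). Axin2 and Lef1, direct targets, were below the filter. Axin2 was at 0.372 ± 0.258 RPKM in WT and 0.306 ± 0.237 RPKM in CKO, and Lef1 at 0.0492 ± 0.0472 and 0.0748 ± 0.0356 RPKM.

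Of 17 tested osteoblast lineage genes, 15 lay below 0 and the median log2 difference was −1.08, while the values of Runx2, an osteoblast transcription factor gene, overlapped. Bmp4 was at 45.6 ± 2.84 RPKM in WT and 8.94 ± 8.13 RPKM in CKO, Pth1r, the parathyroid hormone receptor gene, at 7.07 ± 3.23 and 2.72 ± 0.941 RPKM, and Omd, the osteomodulin gene, at 132 ± 173 and 2.25 ± 1.84 RPKM. Alpl, the alkaline phosphatase gene, was at 11.5 ± 10.1 and 2.44 ± 3.74 RPKM. Runx2 was at 6.82 ± 2.81 RPKM in WT and 6.33 ± 3.06 RPKM in CKO, Col1a1 at 2259 ± 327 and 1983 ± 922 RPKM, and Spp1, the osteopontin gene, at 3385 ± 3513 and 1014 ± 596 RPKM. Sp7 was at 1.70 ± 2.09 RPKM in WT and 0.188 ± 0.325 RPKM in CKO and below the filter, and Bglap was not analysed here. None of the 17 members passed over all genes. Adjusted over the list alone, 5 passed, all lower: Ibsp, Bmp4, Omd, Pth1r and Cdh11, of which Cdh11 was named after its values were seen. As a set the list passed as lower (limma camera adjusted p = 8.17e-06), but not with an estimated correlation (adjusted p = 0.515). The median was −0.42 without WT library 2, −0.57 without CKO library 3 and −0.52 without the filter on low values. Ibsp was below the filter, and so not tested, with any 1 WT library left out and with the filter at RPKM 5. The 5 became 8 without CKO library 1, 3 without CKO library 3, 1 without WT library 1 or CKO library 2, and 0 without WT library 2 or WT library 3. They were 3 after median centring, 2 with the WT libraries of 1 animal label merged, 1 after quantile normalization, without a filter or with voom on recovered reads, and 0 with the filter at RPKM 5.

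The median log2 difference of the 19 tested adipocyte lineage genes was −0.23, with 8 above and 11 below 0. Pparg, the master regulator of fat cell formation, was at 2.32 ± 0.115 RPKM in WT and 0.990 ± 0.780 RPKM in CKO. Cebpa was at 11.9 ± 2.57 and 4.80 ± 2.22 RPKM, Cebpd at 66.4 ± 32.1 and 30.6 ± 13.2 RPKM, and the lipid droplet gene Plin4 at 1.33 ± 0.319 and 0.276 ± 0.0460 RPKM. Lpl, the lipoprotein lipase gene, was at 20.3 ± 11.96 and 5.95 ± 6.50 RPKM. Fabp4, a fatty acid carrier gene, was at 7.70 ± 8.28 RPKM in WT and 16.5 ± 13.6 RPKM in CKO. Adipoq was under 0.5 RPKM in every library. Lpl was highest in WT library 3 (33.53 RPKM) and, within CKO, in CKO library 3 (13.29 RPKM). These libraries also had the highest macrophage marker levels. Fabp4 was highest in CKO library 3 (31.76 RPKM) but, within WT, in WT library 1 (17.04 RPKM). Since the cultures held macrophage transcripts, Lpl and Fabp4 are not read as levels of fat cells alone. None of the 19 members passed over all genes or adjusted over the list alone, and the list was not called as a set (limma camera adjusted p = 0.1). Without CKO library 3, which had the highest Fabp4, the list passed as lower (adjusted p = 0.0233, and 0.562 with an estimated correlation), and 1 member passed as lower over the list alone. The median was −0.02 without WT library 1, −0.05 without WT library 3, −0.09 without CKO library 2, −0.06 after quantile normalization, −0.13 without a filter and 0.13 with the filter at RPKM 5. Over the list alone, 2 members passed as lower without a filter, 1 with voom on recovered reads and 3 with a macrophage covariate.

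All 10 tested chondrocyte lineage genes lay below 0, and their median log2 difference of −3.04 was the largest of the 22 tested lists. Comp, a cartilage and tendon matrix gene, was at 732 ± 849 RPKM in WT and 2.62 ± 2.20 RPKM in CKO. Cnmd, the chondromodulin gene, was at 797 ± 980 and 0.694 ± 1.05 RPKM, and Hapln1, a hyaluronan link protein gene, at 13.9 ± 5.90 and 0.751 ± 0.892 RPKM. The large SDs of Comp and Cnmd came from WT library 2, where they reached 1707 and 1895 RPKM, while WT library 1 held 152 and 13.1 RPKM. Col2a1, a list member chosen after its values were seen, was at 1.09 RPKM in CKO library 3. It was at 84.4 RPKM or more in every other library, CKO libraries 1 and 2 included. None of the 10 passed over all genes, and 7 passed as lower when adjusted over the list alone (6 to 8 with 1 library left out). As a set the list passed (limma camera adjusted p = 3.48e-10), but not with an estimated correlation (adjusted p = 0.515). The median was −1.89 without the filter on low values. By library the list averaged 2.83, 4.38 and 3.10 in WT and 1.75, 1.23 and 0.53 in CKO on the log2(RPKM + 1) scale.

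Genes of the extracellular matrix and metalloprotease lists went both ways. Fmod, the fibromodulin gene, was at 966 ± 727 RPKM in WT and 13.7 ± 18.9 RPKM in CKO. The collagen crosslinking genes Loxl2 and Loxl1 were at 24.7 ± 10.8 and 64.3 ± 19.0 RPKM in WT and at 125 ± 22.3 and 152 ± 23.7 RPKM in CKO, and Tnc, the tenascin C gene, was at 138 ± 80.4 and 348 ± 23.2 RPKM. The collagenase gene Mmp13 was at 243 ± 209 and 19.4 ± 31.2 RPKM, and the stromelysin gene Mmp3 at 146 ± 146 and 10.7 ± 10.5 RPKM. None of the 27 matrix or 12 metalloprotease genes passed over all genes. Adjusted over the list alone, Loxl1 and Loxl2 passed as higher and Fmod as lower, and no metalloprotease gene passed. The matrix count was 2 higher and 5 lower without CKO library 1, 1 higher and 1 lower without CKO library 2, and 1 higher and 2 lower without WT library 3, and it was 4 higher and 1 lower with the WT libraries of 1 animal label merged and 1 higher and 1 lower with a macrophage covariate. The metalloprotease count was 2 lower without CKO library 3. Neither list was called as a set (limma camera adjusted p = 0.174 for each), though the matrix list passed as lower without CKO library 1 (adjusted p = 0.00584, and 0.41 with an estimated correlation). Of the 21 BMP and TGF-β targets, Id2, Nog and Bmp4 passed as lower over the list alone, with Nog, a BMP antagonist gene, at 5.91 ± 3.05 RPKM in WT and 1.05 ± 0.630 RPKM in CKO. This count was 5 without CKO library 1, 1 without WT library 2 or CKO library 3, and 0 without WT library 1, WT library 3 or CKO library 2, and the list was not called (adjusted p = 0.0864). It passed as lower without WT library 2 (adjusted p = 0.0264), WT library 3 (0.035), CKO library 1 (0.0216) or CKO library 2 (0.0167), but in none of these with an estimated correlation (adjusted p = 0.518 to 0.709). Its median, −0.56 in all libraries, was −0.29 without WT library 2 and −0.12 without CKO library 3. The count of 3 was 0 after quantile normalization, with voom on recovered reads and with the filter at RPKM 5. Nog was below that filter, and the median there was 0.35. The list passed as lower with a macrophage covariate (camera adjusted p = 0.04, and 0.636 with an estimated correlation).

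Of 14 tested smooth muscle and myofibroblast genes, 13 lay above 0, with a median log2 difference of 1.12. Myh11, the smooth muscle myosin gene, was at 1.35 ± 1.04 RPKM in WT and 9.95 ± 5.12 RPKM in CKO, Des, the desmin gene, at 0.645 ± 0.589 and 7.43 ± 5.40 RPKM, and Cnn1, the calponin gene, at 145 ± 79.9 and 529 ± 302 RPKM. Actg2, a smooth muscle actin gene, was at 83.2 ± 98.7 and 511 ± 259 RPKM, and at 1.10 RPKM in WT library 2. None passed over all genes, and Myh11 and Des passed as higher adjusted over the list alone. Both were below the filter, and so not tested, when it was set at RPKM 5. As a set the list passed as higher (limma camera adjusted p = 8.17e-06), but not with an estimated correlation (adjusted p = 0.515). The median was 0.57 without WT library 2 and 0.72 without CKO library 2, and the count over the list alone was 0 without either, 0 with the filter at RPKM 5 and 1 with voom on recovered reads.

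Among the 20 tested marrow stromal cell markers, Mcam, a pericyte and progenitor surface marker gene, was at 3.49 ± 2.46 RPKM in WT and 36.4 ± 28.5 RPKM in CKO, and Nes, the nestin gene, at 2.35 ± 2.13 and 15.6 ± 9.52 RPKM. Cspg4, the NG2 proteoglycan gene of pericytes, was at 12.1 ± 4.84 and 1.59 ± 1.43 RPKM, and Angpt1, a niche factor gene, at 4.42 ± 1.48 and 0.868 ± 0.452 RPKM. None passed over all genes with limma. Adjusted over the list alone, Mcam passed as higher and Cspg4 and Angpt1 as lower, and the list was not called as a set (camera adjusted p = 0.135) but passed as lower without WT library 3 (adjusted p = 0.0373, and 0.563 with an estimated correlation). The count was 2 higher and 4 lower without CKO library 1 and 2 higher and 2 lower without WT library 3. It was 1 higher and 4 lower without CKO library 3 and 1 higher and 3 lower without WT library 1. It was 2 higher and 3 lower after quantile normalization and 1 higher and 1 lower with the filter at RPKM 5. Angpt1 was below that filter.

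Stress, metabolic and cell cycle genes passed as sets with camera: the unfolded protein response (limma adjusted p = 7.22e-05), glycolysis (adjusted p = 0.00199) and cell cycle lists (adjusted p = 0.00123) as higher and the sterol list as lower (adjusted p = 2.37e-04). With an estimated correlation none did: adjusted p = 0.515 for the unfolded protein response and sterol lists, 0.633 for glycolysis and 0.637 for the cell cycle. No member passed over all genes or over its list alone. All 19 genes of the ATF4 and unfolded protein response list lay above 0 (median log2 difference 0.68). Psat1, a serine synthesis gene, was at 97.9 ± 47.1 RPKM in WT and 162 ± 20.9 RPKM in CKO, and Ddit3, the CHOP gene, at 16.1 ± 7.46 and 38.1 ± 27.5 RPKM. Of 20 glycolysis and hypoxia genes, 18 lay above 0 (median 0.41), with Vegfa at 29.9 ± 14.0 and 91.4 ± 56.4 RPKM and Hk2, a hexokinase gene, at 7.10 ± 3.85 and 18.1 ± 11.8 RPKM. Of 23 cholesterol and fatty acid synthesis genes, 21 lay below 0 (median −0.36), with Srebf1, a regulator of lipid synthesis, at 25.7 ± 9.64 and 13.8 ± 2.36 RPKM, Hmgcs1 at 35.0 ± 7.53 and 22.3 ± 4.29 RPKM and Idi1 at 6.43 ± 0.848 and 3.79 ± 0.795 RPKM. Of 30 cell cycle genes, 29 lay above 0 (median 0.78), with Aurka at 10.2 ± 10.0 and 18.7 ± 7.83 RPKM and Ube2c at 34.3 ± 32.9 and 63.0 ± 27.7 RPKM. Ube2c was at 1.04 RPKM in the passage 7 library. The cell cycle median was −0.15 without WT library 2 (adjusted p = 0.509), 1.53 without WT library 1, 1.5 with voom on recovered reads and 0.48 without CKO library 1 (adjusted p = 0.0564), and the glycolysis call ended without CKO library 3 (median 0.24, adjusted p = 0.185) and after quantile normalization (median 0.27, adjusted p = 0.0792). The unfolded protein response median was 0.42 without CKO library 3, and the sterol median was −0.24 without WT library 2.

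**Figure D2:**
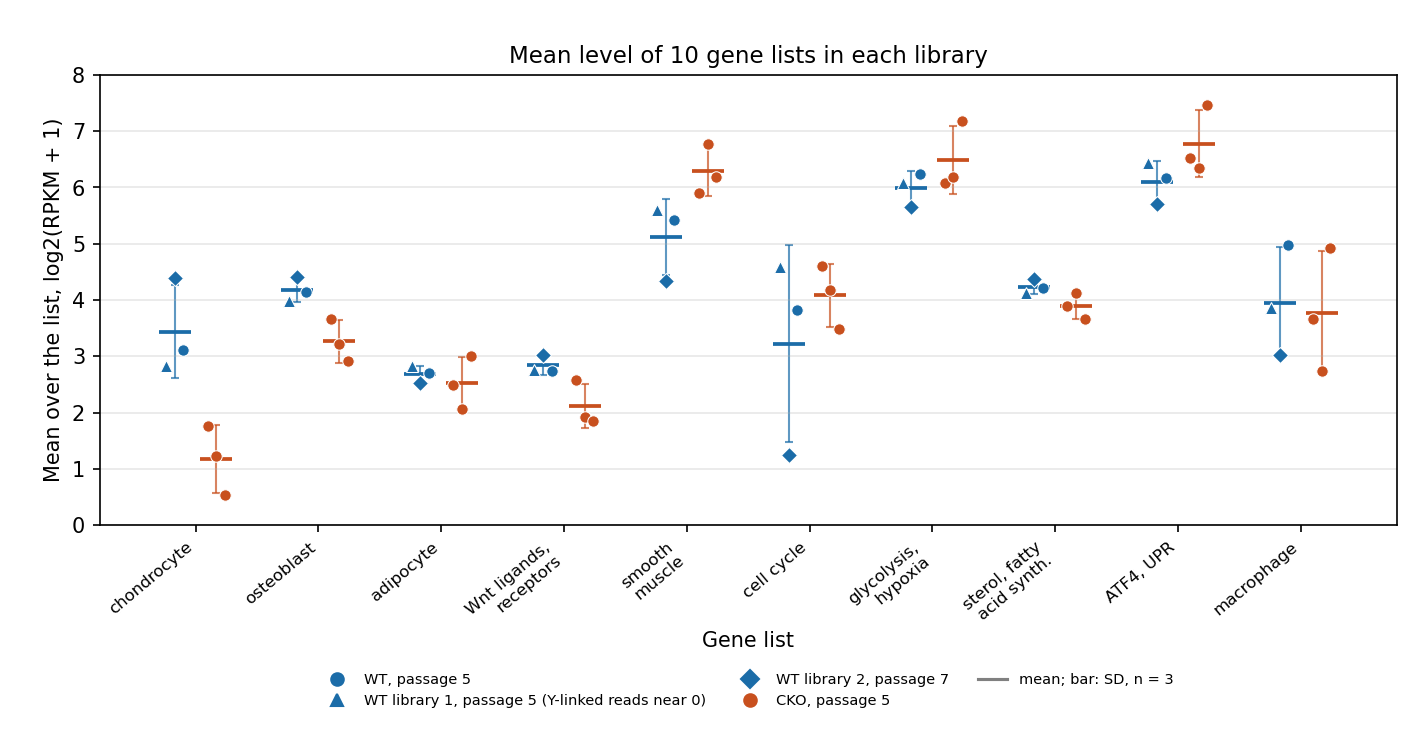
Mean level of 10 gene lists in each library, as log2(RPKM + 1) over the listed genes on the vertical axis, with WT in blue and CKO in orange, bars for the mean and SD over n = 3, a triangle for WT library 1 and a diamond for WT library 2 (passage 7). The chondrocyte points of the 3 CKO libraries (0.53 to 1.75) lie below those of the 3 WT libraries (2.83 to 4.38), while the cell cycle point of WT library 2 (1.25) lies below all others.

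Immediate early, inflammatory, YAP/TAZ, p53, interferon and Notch genes were not called as sets over the 6 libraries, and 3 of these lists passed with 1 library left out, none of them with an estimated correlation. The immediate early list (median log2 difference 0.31, limma camera adjusted p = 0.122) had Ier3 at 69.4 ± 42.9 RPKM in WT and 169 ± 99.6 RPKM in CKO and Myc at 23.8 ± 21 and 47.8 ± 5.15 RPKM. It passed as higher without WT library 1 (median 0.80, adjusted p = 0.00569) or WT library 3 (0.66, adjusted p = 0.0182) and with a macrophage covariate (adjusted p = 0.0342), but in none of these with an estimated correlation (adjusted p = 0.563 to 0.7). Its median was −0.24 without WT library 2, 0.48 without CKO library 2 and 0.19 with the WT libraries of 1 animal label merged. Of the inflammatory genes (median 0.63, adjusted p = 0.111), Ptgs2, the inducible cyclooxygenase gene, was at 34.6 ± 40.7 and 172 ± 88.4 RPKM, Il11 at 1.06 ± 1.04 and 6.58 ± 4.04 RPKM, Lif at 5.13 ± 4.14 and 14.6 ± 4.87 RPKM, and Il33 at 5.74 ± 6.17 and 0.488 ± 0.289 RPKM. None of the 19 passed over the list alone, but 3 did as higher without WT library 1, 1 without CKO library 3 and 2 with the WT libraries of 1 animal label merged. As a set the inflammatory list passed as higher without WT library 1 (adjusted p = 0.00892), WT library 3 (0.0182), CKO library 1 (0.0426) or CKO library 2 (0.0369), without a filter (0.0331) and with a macrophage covariate (0.0284), but in none of these with an estimated correlation (adjusted p = 0.563 to 0.855). Its median was 1.15 without WT library 1, 1.32 without CKO library 2, −0.05 without WT library 2, −0.11 without CKO library 3 and 0.41 with the filter at RPKM 5. The YAP/TAZ list (median 0.07, adjusted p = 0.801) held F3, the tissue factor gene, at 92.7 ± 56.5 and 392 ± 168 RPKM and Axl at 70.8 ± 28.1 and 132 ± 38.9 RPKM, and without CKO library 1 it had 2 members higher and 1 lower over the list alone. Its median was −0.10 and −0.13 without WT libraries 1 and 3, and 0.10, −0.05 and 0.03 without CKO libraries 1 to 3. It was −0.06 after quantile normalization, 0.14 with the WT libraries of 1 animal label merged and −0.001 with a macrophage covariate. The p53 list (median 0.30, adjusted p = 0.135) held Ccng1 at 86.9 ± 18.8 and 143 ± 37.5 RPKM, and its median was 0.49 without CKO library 1 and 0.17 without CKO library 3. The interferon list had a median of −0.03 (adjusted p = 0.801) and passed as lower without CKO library 3 (median −0.49, adjusted p = 2.51e-04), but not with an estimated correlation (adjusted p = 0.569). Its median was 0.40 without CKO library 1 (adjusted p = 0.0981), 0.25 without CKO library 2, 0.10, −0.26 and 0.18 without WT libraries 1 to 3, and −0.09 to 0.10 under the other alternatives. The Notch list (adjusted p = 0.801) held Notch2 at 14.4 ± 3.16 and 9.86 ± 3.97 RPKM. Median and mean differ in sign for the interferon (mean 0.01) and Notch lists (median 0.06, mean −0.02), and in the MAPK7 cascade list (median 0.01, mean −0.42). The Notch median was 0.13 and −0.38 without WT libraries 1 and 2 and −0.03, 0.09 and −0.04 without CKO libraries 1 to 3, and the MAPK7 cascade median was 0.05, −0.08 and −0.05 without WT libraries 1 to 3 and −0.12, 0.03 and −0.18 without CKO libraries 1 to 3.

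Of the markers of other marrow cells, those of macrophages were the most abundant. Csf1r, the macrophage growth factor receptor gene, was at 20.3 ± 18.1 RPKM in WT and 9.15 ± 3.88 RPKM in CKO, and Laptm5 at 21.5 ± 17.2 and 13.3 ± 8.69 RPKM. Of 4 tested osteoclast markers, none passed, with Ctsk, the cathepsin K gene that fibroblasts also express, at 75.2 ± 16.9 and 48.4 ± 7.90 RPKM. Of the endothelial markers 2 were tested: Erg, at 3.26 ± 1.99 and 0.223 ± 0.222 RPKM, passed as lower when adjusted over the list alone, and Egfl7, at 1.86 ± 0.896 and 3.07 ± 0.729 RPKM, did not. Erg was below the filter with any 1 WT library left out. Of 4 tested skeletal muscle genes none passed, with Acta1 at 14.7 ± 12.7 and 34.0 ± 26.6 RPKM. A single granulocyte marker was tested and did not pass, and no lymphocyte or erythroid marker reached the filter.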

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

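The voom fit on recovered reads, the fit with a macrophage covariate and the estimated correlation together with each other alternative run for lists were chosen after the data were seen. Mapk7, Lrp6 and Ctnnb1 stayed lower in CKO and short of the limma threshold in each of the 16 alternatives run for them. With 1 library left out the log2 difference ran from −0.62 to −0.40 for Mapk7, from −1.84 to −1.06 for Lrp6 and from −0.32 to −0.02 for Ctnnb1, and over all alternatives the adjusted p ran from 0.416 to 0.849, 0.139 to 0.832 and 0.74 to 1. The count of genes that differ, 1 as reported, ran from 0 to 24 with 1 library left out. It was 2 after median centring and 2 after quantile normalization, both higher in CKO (Galnt16 and Lrrc15). It was 4 with the filter at RPKM 5 (Galnt16, Prelp, Klf2 and Prg4; fewer genes are tested), 0 without a filter (1399 genes at an unadjusted p under 0.05), 0 with a pseudocount of 0.1 (1059 genes), 0 with voom on recovered reads (1000 genes) and 0 with the macrophage covariate (1105 genes). Merging the WT libraries that share an animal label gave 50 genes (8 higher, 42 lower), but the Y-linked genes do not bear out that label. At an adjusted p under 0.1 there were 5 genes, and at an unadjusted p under 0.05 with a fold of at least 2 there were 579 (174 higher, 405 lower). Galnt16 kept its direction in the 16 alternatives run for it, with an adjusted p of 0.00935 to 0.256, above 0.05 in 9 of them. The cause of these shifts was not tested.

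The replicate numbers of the titles do not pair the libraries: the deviations of same-numbered libraries correlated at 0.198, 0.014 and −0.019, and the replicate block gave 0 genes, with 1123 at an unadjusted p under 0.05. By these deviations WT library 1 correlated best with CKO library 1, but WT library 3 did so with CKO library 2 (0.206). The deviations of WT library 2 correlated at −0.038 to 0.017 with those of the CKO libraries. The 8 lists called by camera became 0 with fry and 0 with an estimated correlation, alone or together with any of the other alternatives run for lists. Those alternatives, the block included, left the count within 1.5 times at the preset correlation. Adjusted over the list alone, the block gave 4 lower in the Wnt list, 2 higher and 4 lower in the stromal list, 3 lower in the adipocyte list, 1 higher and 3 lower in the β-catenin target list, 1 higher and 1 lower in the matrix list and none in the smooth muscle list. The cell cycle median ran from −0.15 to 1.53 with 1 library left out, and over its alternatives the adjusted p ran from 1.81e-07 to 0.698. Over theirs the chondrocyte list ran from 6.64e-12 to 0.515 and the glycolysis list from 3.23e-05 to 0.633. Of the 80 other named genes, 5 turned direction with 1 library left out: Runx2 ran from −0.43 to 0.16, Col1a1 from −0.63 to 0.065, Ddx3y from −0.33 to 1.81, Kdm5d from −0.10 to 1.32 and Eif2s3y from −0.38 to 1.00. In 27 of 1236 pairs of gene and alternative a gene (15 genes in all) newly passed, in 9 one no longer passed, and in 1193 neither changed. Size-factor and upper-quartile scaling and the count-model tests, planned for count tables, were not run: the deposited unit is RPKM, and the recovered reads were tested with voom alone. Depth limits low genes: 3 reads are an RPKM of 0.145 to 0.173 for a gene of 1 kb.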

Other observations

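The genes of this and the next paragraph were chosen after their values were seen, and so were the counts of genes apart in 1 library, the tests of depth and of the shared animal label, the macrophage covariate, the chondrocyte median over the splits, and the use of the planned fits without WT library 1 or 2 to weigh the chondrocyte and cell cycle lists. 2 genes for secreted proteins that sit in no list were far higher in WT without passing the limma test, and both passed without WT library 1. Penk, the proenkephalin gene, was at 73.1, 6551 and 1669 RPKM in WT libraries 1 to 3 and at 10.9, 2.30 and 1.13 RPKM in CKO. Clu, the clusterin gene, was at 17.9, 466 and 228 RPKM in WT and at 3.50, 3.98 and 5.64 RPKM in CKO. Cxcl12, a niche chemokine gene among the stromal markers, was at 91.5 ± 45.3 RPKM in WT and 35.6 ± 8.50 RPKM in CKO (n = 3 each).

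Counts of genes apart in 1 library covered only genes with a high mean RPKM and without a predicted or clone name, not all genes. The passage 7 library (WT library 2) had 120 such genes more than 1 log2 unit above and 326 as far below the other 5 libraries. Among those above, Pcp4 had the widest gap, at 217 RPKM against at most 1.89, and Ucma was at 454 RPKM against at most 33.9, Cilp2 at 64.1 against at most 0.272 and Scrg1 at 186 against at most 8.59 RPKM. CKO library 3 had 80 genes above and 73 below. Arg1, an arginase gene of alternatively activated macrophages, was at 131 RPKM there against at most 0.490, Saa3, an acute phase gene, at 526 against at most 6.95 and Ccl6 at 786 against at most 29.99 RPKM. Its unfolded protein response list averaged 7.46, with 5.71 to 6.53 elsewhere, and Hspa5, the BiP chaperone gene, reached 3821 RPKM against at most 740 RPKM. CKO library 1 retained Sfrp2 at 54.2 RPKM, Ccn3 at 61.4 RPKM and Svep1 at 69.0 RPKM, where CKO libraries 2 and 3 had at most 0.929, 2.36 and 9.55 RPKM. In CKO library 2, Pdgfra, a stromal marker gene, was at 1.01 RPKM against at least 9.82, and Dcn, the decorin gene, at 7.49 against at least 58.3 RPKM.

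Y-linked reads were near 0 in WT library 1 alone: 14 reads over 4 genes, against 1901 to 3616 in the other 5 libraries. Low depth is argued against, since its total is at least 0.84 of that of each other library. Cells of the same animal at 2 passages, as the shared animal label of WT libraries 1 and 2 states, are also argued against: 14 reads (Poisson 95% interval 7.7 to 23.5) are 0.46% of the 3033 that the level in WT library 2 gives. The interval covers counting error only, not the spread between libraries. A female animal is a candidate explanation. The X-linked partner genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape X inactivation, were highest in WT library 1 in 4 of 4 cases. The lead was small for Ddx3x (103 RPKM, with 102 in CKO library 3) and for Kdm6a (5.055 RPKM, with 4.471 in CKO library 3). Xist had no listed value and could not be checked. Which label is wrong, and whether sex adds to the spread within WT, stays open.

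The chondrocyte list was lower in the 3 CKO libraries, with a median log2 difference of −3.04. The passage 7 library as the whole cause is argued against by a median of −2.63 without it. Without WT library 1 the median was −3.27. That library had the lowest list level in WT (2.83, with 4.38 and 3.10 in WT libraries 2 and 3). Leaving it out was nearly bound to widen the difference, so this median decides nothing about WT library 1. A difference in macrophage content is argued against as the whole cause by −3.14 with the marker level as a covariate. The largest absolute median of the list over the other 9 splits of the 6 libraries was 1.97. A smaller value there was nearly fixed in advance, since the list level lay lower in the 3 CKO libraries than in every WT library. No conclusion is drawn from it. The genotype, and differences between the animals or cultures that happened to be in each group, stay open and untested against each other.

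The cell cycle list was higher in CKO as a set with camera, with a median log2 difference of 0.78, but not with an estimated correlation (adjusted p = 0.637). The passage 7 library alone may account for this, since the median was −0.15 without it, and that library had the lowest cell cycle level (1.25, with 3.49 to 4.60 in the others). A slower cycle at the later passage is a hypothesis that 1 library cannot test.

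The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene past the threshold, and the highest of the others gave 0, so 1 of 10 splits gave as many. For gene lists the real split gave 8, the highest other 13, and 6 of 10 splits gave at least as many. The split of WT library 1 with CKO libraries 1 and 3 against the rest had 1650 genes at an unadjusted p under 0.05, where the real split had 1080.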
